A study of Mus musculus with 115 samples.

How the data were processed

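Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was read out in 115 libraries of mouse bone marrow-derived macrophages, which are grown from bone marrow in medium that drives cells to the macrophage lineage. The targets were H3K4me1 (39 libraries), H3K27ac (25), H3K4me3 (11), PU.1 (23), Stat6 (6), Stat1 (6), JunB (2) and RNA polymerase II (3). Groups were taken from the sample titles: 47 libraries formed the stimulus panel, 12 each the Stat6 KO, Stat1 KO and IFNg time course experiments, 18 the IL4 time course and 4 each the IL4 and IFNg washouts. Another 6 libraries named no experiment. Control cells were BALB/c for Stat6 KO and 129S6 for Stat1 KO. Doses were 10 ng/ml for IL4, LPS, TNFa and IL1b, 100 ng/ml for IFNg, 1 ng/ml for TGFb1 and MALP2, and 100 nM for CpG, per the labels.

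Each library came as 1 list of called peaks. Reads were aligned with Bowtie 0.12.7 to mm9 and peaks called with MACS 1.4, per the submitters' processing notes; the caller's settings, and any filter of the lists, are not given in the sources used here. Each deposited list gave a position and a score per peak, with a lowest score of 50 in the lists, and the layout is that in which this caller writes a score computed from its p-value. The score is the authors' own value and was used only to rank or filter peaks within a list. No counts of reads came with the lists, so read depth is unknown and the number of peaks is the only size measure. It ranged from 54580 to 114362 for H3K4me1, from 30451 to 44011 for H3K27ac, from 16879 to 19818 for H3K4me3, from 70069 to 120394 for PU.1, from 4818 to 33066 for Stat6 and from 899 to 29641 for Stat1. A peak that is missing from a list may have fallen under the caller's threshold, so a share of regions with a peak measures detection and not the height of the signal. Over 1383 pairs of libraries of the same target, at most 0.0279% of the peaks of the shorter list had identical ends in the other, and every library was counted on its own.

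Peaks were compared by overlap of at least 1 bp. Regions gained under a stimulus were the peaks of a panel library that overlapped no peak of either untreated panel library of the same target. Latent regions were gained H3K4me1 regions that also overlapped no untreated H3K27ac or PU.1 peak of the panel and no H3K4me3 peak of any panel library. For the tests, regions were defined in the panel and counted in the libraries of the other experiments, so the library was the replicate. Two-sided exact permutation tests over libraries compared the mean shares, with a threshold of 0.05. Where each condition had a single library, values were given with 95% Wilson intervals and without a test. The intervals cover counting error only, and regions are not replicates. For factor binding, a region counted as bound where it overlapped a peak in any stimulated library of the factor, and 10000 random draws of the same number of peaks were taken from peaks of the same library that overlapped an untreated peak, matched on 20 classes of width. Positions are 1-based mm9 coordinates.

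The regions named by position followed a fixed rule. For IL4 and for IFNg these were the 10 gained H3K4me1 regions with the highest score among those with a peak in every other wild-type library of that stimulus at 4, 24 or 72 h and in none of the wild-type untreated libraries. For LPS they were the 5 highest among latent regions with H3K27ac and PU.1 at 4 h and H3K4me1 at 24 h, and for each other stimulus the 2 highest among latent regions with H3K27ac. Chromosome 18 was left out of the named regions. The groups, the tests, this rule and most alternative settings were fixed before the data were examined.

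The alternatives fixed then were a score of at least 100, an overlap of 50% of the shorter peak, a distance of more than 1000 bp to any untreated peak, only the untreated panel library of the same file style, equal numbers of peaks per library, treated minus untreated within each experiment, each tested library left out in turn, a stricter set of regions at 24 h in the washouts, and exchanged labels of the Stat6 KO H3K27ac libraries, whose labels and file names give opposite treatments. The panel files came in 2 styles, with LPS and untreated replicate 1 in the first and the other stimuli and untreated replicate 2 in the second; the libraries of the other experiments were set against untreated replicate 2 under that alternative. Alternatives added after seeing the data were draws matched also on 5 classes of score, the share of gained peaks without LPS or without each untreated library in turn, the IL4 and IFNg tests on shares minus those of TGFb1-gained regions in the same library, for all of these or only those without a panel peak under the stimulus, the first 4 settings applied to the counts of replicated regions, to the shares of newly acetylated regions and to H3K27ac at 15 min of IL4, tests within libraries with or lacking peaks on chromosome Y, and treated minus untreated within experiments for H3K27ac under IL4 and PU.1 under IFNg. The 4 settings were also applied to the shares of gained peaks.

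Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used. The calculation was tested on simulated data: of 21200 simulated stimulated peaks, all 1200 planted gained regions were recovered and 0 others were called. Every other simulated peak had an untreated copy that overlapped it. The simulation therefore checks the code and not how often real lists give false gains. Overlaps of 400 simulated regions differed from a brute-force search in 0 cases, the permutation p differed by 0 from a reference implementation in 20 tests, and 4.5% of 400 data sets without an effect gave a p of 0.05 or less. Gene lists fixed at the start were not tested, since no mm9 annotation was used here; the gene table at hand describes GRCm38.p6, another build, and no coordinates were joined to it. Regions are therefore given by position without a gene.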

Results

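The study mapped histone marks and transcription factors in mouse bone marrow-derived macrophages before and after stimulation, to find regulatory regions that appear only once cells are stimulated. H3K4me1 marks enhancers, H3K27ac active enhancers and promoters, and H3K4me3 active promoters, while PU.1 is the factor that establishes the macrophage lineage. The panel covered 8 stimuli at 4 h: LPS, a bacterial ligand of Toll-like receptors, MALP2 and CpG, ligands of other Toll-like receptors, and the cytokines IFNg, IL4, TNFa, TGFb1 and IL1b. LPS was also applied for 24 h. Most conditions had a single library per target. The labels do not say whether libraries came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Intervals in parentheses are 95% Wilson intervals of a single library. Shares without one that rest on a set of at least 3659 gained regions had intervals of at most 1.61 points to either side. Shares of smaller sets can have wider ones. These intervals cover counting error only.

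Every stimulus was accompanied by H3K4me1 peaks at places without a peak in either untreated panel library. At 4 h, LPS had 11035 such gained regions, MALP2 8088, CpG 7665, TNFa 6505, IL4 5957, IFNg 5895, IL1b 4965 and TGFb1 4815. As shares of each library's peaks these ranged from 6.09% for TGFb1 (5.92 to 6.26) to 10.5% for LPS (10.3 to 10.7). Wild-type untreated C57BL/6 libraries of the other experiments, treated in the same way, gave 6.21% ± 1.76 (SD, n = 4), against 7.77% ± 1.43 (SD, n = 8) for the stimulated libraries. Untreated BALB/c and 129S6 cells gave 10.2% and 8.39%. The difference of 1.56 points did not pass the two-sided exact permutation test (p = 0.141), and stimulation and experiment coincide in it. Without the untreated library of the IFNg time course, at 3.60%, it was 0.692 points (exact permutation p = 0.461), and more than 1000 bp from an untreated peak it was 0.565 points (exact permutation p = 0.428). It turned to -2.09 points (p = 0.131, exact permutation test) with the untreated library of the same file style alone, where LPS gave 14.4% and MALP2 16.4%, and to -0.729 points (p = 0.479, exact permutation test) with peaks of a score of at least 100.

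Gains of H3K27ac separated the stimuli more widely. LPS had 9668 gained H3K27ac regions, 28.4% of its H3K27ac peaks (27.9 to 28.9), and IFNg 6826, or 20.4% (19.9 to 20.8). CpG and MALP2 followed with 18.8% and 18.5%. TNFa had 14.8%, IL4 14.4%, IL1b 13.2% and TGFb1 11.6% (11.2 to 11.9). LPS had the highest and TGFb1 the lowest of the 8 H3K27ac shares under each of the 4 alternative settings as well. Untreated H3K27ac libraries of the other experiments gave 5.77% in the IL4 time course, 17.6% in 129S6 and 20.0% in BALB/c cells. The shares of TNFa, IL4, IL1b and TGFb1 thus lay above the only other untreated library of the same strain and below both other strains. The gained shares were smallest for H3K4me3, at 1.93% (IL4) to 4.19% (CpG) of peaks at 4 h. The file name of the IL4 library has an unexplained addition; the next lowest was TGFb1, at 2.03%. Gained PU.1 peaks made up 10.6% (TGFb1) to 17.1% (LPS). Untreated PU.1 libraries of the other experiments gave 4.12% (IFNg time course), 8.50% (BALB/c) and 9.65% (129S6). The untreated panel libraries also differed from each other. Of the H3K4me1 peaks, 23.5% of replicate 1 were absent from replicate 2 and 9.74% the other way. These shares were 15.8% and 9.06% for H3K27ac, 3.34% and 22.4% for H3K4me3, and 14.5% and 17.1% for PU.1. The LPS libraries and untreated replicate 1 held peaks on chromosome Y and those of the other stimuli and untreated replicate 2 held none, so LPS is compared with the other stimuli across this split. With each stimulus set against the untreated library on its own side, LPS still had the highest share for H3K27ac (30.6%, against at most 24.7%) and PU.1 (23.3%, against at most 19.7%), but not for H3K4me1. The PU.1 list of untreated replicate 1 had narrower peaks (median width 397 bp, 50.6 Mb covered) than that of replicate 2 (739 bp, 87.1 Mb). This favours a higher PU.1 share for LPS. Another effect of the split on the LPS shares cannot be separated from LPS.

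Latent regions, which lacked H3K4me1, H3K27ac and PU.1 in untreated cells and had no H3K4me3, made up most of each gained set. There were 6785 under LPS, 5970 under MALP2, 5789 under CpG, 4884 under TNFa, 4337 under IL4, 4276 under IFNg, 3586 under IL1b and 3563 under TGFb1. Of the latent regions, 31.6% had H3K27ac at 4 h of LPS (30.5 to 32.7), 24.0% under IFNg (22.8 to 25.3) and 19.4% under CpG (18.4 to 20.5). The share was 8.48% under IL1b (7.61 to 9.43), the lowest of the 8 stimuli. PU.1 was found at 22.3% of the latent regions of IFNg (21.1 to 23.6), 16.6% of those of IL4 (15.5 to 17.8) and 15.0% of those of LPS (14.1 to 15.8). The LPS PU.1 list had narrower peaks (median width 498 bp, 62.5 Mb covered) than that of IFNg (741 bp, 89.8 Mb). This favours fewer overlaps under LPS. The same rule applied to untreated libraries of the other experiments returned 760 to 4839 regions. H3K27ac lay at 1.74% of these in the IL4 time course (1.30 to 2.33), 18.4% in BALB/c and 26.7% in 129S6 cells. PU.1 lay at 21.4% in BALB/c, 21.3% in 129S6 and 12.2% in the IFNg time course (10.1 to 14.8), so its shares under the stimuli did not stand out from untreated cells. The counts depended on the rule: regions more than 1000 bp from an untreated peak numbered 4398 under LPS and 2671 under IL4, and the untreated library of the same file style alone raised IL4 to 7220 and IFNg to 7173.

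The 5 LPS regions named by the fixed rule, which asks for H3K27ac and PU.1 at 4 h, all had H3K27ac also at 24 h and a JunB peak under LPS. The strongest lay on chromosome 4 at 134862066 to 134867561 (score 3021), followed by chromosome 2 at 157232497 to 157234527 (score 1876) and chromosome 11 at 97366652 to 97368167 (score 1287). Under TNFa the strongest was on chromosome 1 at 133643349 to 133645556, and under MALP2 on chromosome 6 at 144588392 to 144590999. The leading regions of CpG and IL1b were at the same place on chromosome 12, at 8832779 to 8835037 under CpG and 8832777 to 8835126 under IL1b. Both named TGFb1 regions, the first on chromosome 8 at 72983961 to 72986942, had neither PU.1 under TGFb1 nor H3K27ac at 24 h of LPS.

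Whether gained H3K4me1 recurs in other experiments was tested for IL4 and IFNg. For each stimulus, the 72 h library and a 24 h library came from the same washout experiment and entered as separate replicates. The tests thus treat libraries of the same experiment as independent. IL4-gained regions held an H3K4me1 peak in 39.1% ± 11.8 (SD, n = 5) of cases in wild-type IL4 libraries of other experiments, against 18.2% ± 6.20 (SD, n = 6) in wild-type untreated libraries. Values were 51.1% and 42.0% at 24 h, 47.4% at 72 h, 33.0% at 4 h in BALB/c cells and 21.9% at 4 h in the time course; 4 of the 5 lay above the highest untreated library, at 25.0%. The difference of 20.9 points passed a two-sided exact permutation test (p = 0.00649). Regions gained under TGFb1 also held a peak more often in the IL4 libraries, in 31.6% against 19.0% of cases untreated. The IL4 set minus the TGFb1 set was 7.502 points ± 2.39 (SD, n = 5) in IL4 and -0.829 ± 1.81 (SD, n = 6) in untreated libraries, a difference of 8.33 points (two-sided exact permutation test, p = 0.00216, the smallest possible) with all 5 IL4 libraries above the highest untreated one. IFNg-gained regions held a peak in 40.2% ± 11.3 (SD, n = 4) of cases in IFNg libraries and 19.7% ± 6.45 (SD, n = 6) in untreated ones, a difference of 20.4 points (two-sided exact permutation test, p = 0.00476, the smallest this design allows). All 4 IFNg libraries lay above the highest untreated library, at 26.0%. Minus the TGFb1 set, the IFNg difference was 17.1 points (two-sided exact permutation test, p = 0.00476, the smallest possible). The TGFb1 set was not separate from either stimulus, since 50.6% of it had a panel peak under IL4 and 36.3% under IFNg. With only those of its regions that lacked such a peak, the differences were 14.6 points for IL4 and 20.6 points for IFNg.

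Both calls were lost with the untreated library of the same file style alone, where the differences were 15.9 points for IL4 (exact permutation p = 0.0541) and 14.0 points for IFNg (exact permutation p = 0.138). With equal numbers of peaks per library the IL4 difference was 13.3 points (exact permutation p = 0.00649). Within experiments, where too few were available to reach 0.05, treated minus untreated was 8.02 points in BALB/c cells, -1.66 in the IL4 time course and 24.9 in the IL4 washout, a mean of 10.4 (exact sign-flip p = 0.5, smallest possible 0.25), and 17.7 and 21.7 points for IFNg (exact sign-flip p = 0.5, the smallest possible). Within libraries lacking chromosome Y peaks, IL4-gained regions had a peak in 46.8% ± 4.59 (SD, n = 3) under IL4 and 15.8% ± 6.15 (SD, n = 3) untreated (exact permutation p = 0.1, the smallest possible). Within those with Y peaks, both at 4 h, the values were 27.4% ± 7.87 (SD, n = 2) and 20.5% ± 6.45 (SD, n = 3), with an exact permutation p of 0.6 where 0.1 is the smallest possible. All 4 IFNg libraries lacked Y peaks, and against the 3 untreated libraries lacking them the difference was 22.6 points (exact permutation p = 0.0571, smallest possible 0.0286).

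**Figure D1:**
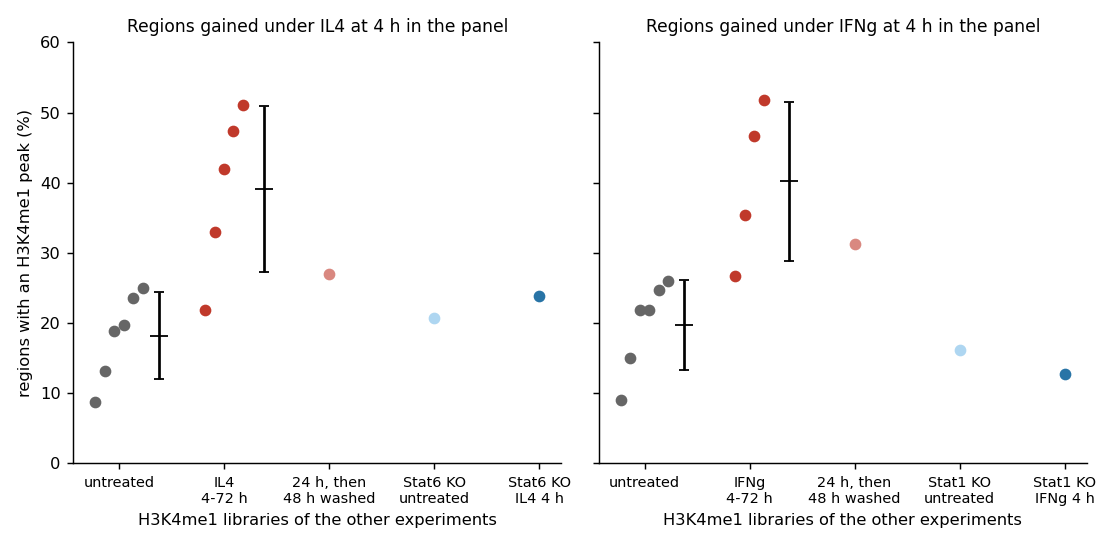
Share of regions gained under IL4 (left) or IFNg (right) at 4 h in the panel, in percent, that held an H3K4me1 peak in libraries of the other experiments; each point is 1 library and the black bars are mean ± SD of the tested groups. IL4 libraries lay between 21.9% and 51.1% and IFNg libraries between 26.8% and 51.8%, against untreated libraries at 8.73% to 25.0% and 9.06% to 26.0%.

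The IL4 and IFNg sets were told apart by the stimulus. In IL4 libraries, IL4-gained regions held a peak more often than IFNg-gained ones, by 7.72 points ± 3.72 (SD, n = 5), and all 5 libraries had a positive difference. In IFNg libraries the same difference was -18.3 points ± 6.03 (SD, n = 4), negative in all 4. The 26.0 points between the groups passed a two-sided exact permutation test (p = 0.00794, the smallest this design allows). Within the libraries lacking Y peaks the difference was 28.6 points (3 IL4 and 4 IFNg libraries; exact permutation p = 0.0286, the smallest possible), and none of the 4 tested IFNg libraries had Y peaks.

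A small set of IL4 regions recurred strictly. Of 5957 IL4-gained regions, 568 had a peak in every other IL4 library, and 110 of these had none in any untreated library. Stat6, the factor activated by the IL4 receptor, bound 95.5% of the 110 at some time of IL4 (89.8 to 98.0) and 0.909% in untreated cells. H3K27ac was present at 81.8% (73.6 to 87.9) and PU.1 at 76.4% (67.6 to 83.3) in the panel at 4 h of IL4, while Stat1 was found at 3.64% (1.42 to 8.98) under IFNg. In Stat6 KO cells 3.64% had H3K4me1 under IL4 (1.42 to 8.98) and 2.73% when untreated. The strongest of the 10 named regions lay on chromosome 9 at 107202076 to 107206791 (score 1996), then chromosome 2 at 93923675 to 93926652 (score 1493), chromosome 3 at 121832979 to 121835109 (score 1382) and chromosome 2 at 103472372 to 103474622 (score 1188). All 10 bound Stat6 and 0 bound Stat1; 9 had H3K27ac, 8 had PU.1, 5 had H3K4me1 after washout and 1 had it in Stat6 KO cells with IL4.

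For IFNg, 778 of 5895 regions had a peak in every other IFNg library and 237 of these had none in an untreated library, or 149 with peaks of a score of at least 100. Stat1, the factor activated by the IFNg receptor, bound 46.4% of the 237 at some time of IFNg (40.2 to 52.8), JunB under LPS 60.8% (54.4 to 66.8) and Stat6 under IL4 13.9% (10.1 to 18.9). H3K27ac was present at 88.2% (83.5 to 91.7) and PU.1 at 67.5% (61.3 to 73.2). In Stat1 KO cells 7.59% had H3K4me1 under IFNg (4.86 to 11.7) and 5.06% when untreated. The strongest named regions were on chromosome 16 at 10814000 to 10815950 (score 1847), chromosome 4 at 149315470 to 149319172 (score 1716) and chromosome 16 again at 10773729 to 10776980 (score 1262). All 10 named IFNg regions had H3K27ac, PU.1 and JunB, 7 bound Stat1, 9 had H3K4me1 after washout and 0 had it in Stat1 KO cells with IFNg. The selection asked for H3K4me1 under the stimulus and its absence when untreated, so these shares describe a strict subset and not the gained regions at large.

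H3K27ac at IL4-gained H3K27ac regions was found in 51.1% ± 17.3 (SD, n = 3) of cases in other IL4 libraries at 2 and 4 h and in 21.2% ± 13.4 (SD, n = 3) in untreated libraries. All 3 IL4 libraries lay above the highest untreated one, and the two-sided exact permutation p of 0.1 is the smallest that 3 against 3 allows, so this design cannot reach 0.05. Without the BALB/c IL4 library the difference of 30.0 points was 19.97 points. PU.1 at IFNg-gained PU.1 regions was found in 20.5% ± 12.9 (SD, n = 3) under IFNg and 11.2% ± 4.87 (SD, n = 3) untreated (two-sided exact permutation p = 0.5, smallest possible 0.1). The IFNg value of 35.2% in 129S6 cells at 4 h stood above 10.9% at 1 h and 15.3% at 2 h in the time course, and without it the difference of 9.28 points was 1.92 points, with untreated cells of other strains kept in. Within experiments PU.1 was higher under IFNg in every case, by 23.2 points in 129S6 cells and by 4.88 and 9.35 points at 1 h and 2 h of the time course, or 17.1, 1.49 and 6.98 points more than at TGFb1-gained regions. The mean over the 2 experiments was 15.2 points (exact sign-flip p = 0.5, the smallest possible). For H3K27ac under IL4 the rises were 37.4 points in BALB/c cells and 34.1 in the time course.

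The KO experiments asked whether gains need Stat6 or Stat1. In BALB/c control cells, H3K27ac at IL4-gained regions was 33.7% untreated (32.4 to 35.1) and 71.1% with IL4 (69.8 to 72.4). In cells labelled Stat6 KO the values were 37.7% (36.3 to 39.1) and 32.8% (31.5 to 34.2). The control change thus exceeded the KO change by 42.2 points for H3K27ac, by 4.95 points for H3K4me1 and by 6.79 points for PU.1. At TGFb1-gained H3K27ac regions, of which 41.1% had a panel peak under IL4 and 33.2% under IFNg, the control change under IL4 was -14.6 points and the KO change -1.53 points. For H3K4me1 the changes at TGFb1-gained regions were 0 and 3.49 points, and for PU.1 -3.00 and -1.16 points. Less these, H3K4me1 changed by 8.02 points in control and -0.417 points in KO cells, and PU.1 by 9.30 and 0.670 points. In 129S6 control cells, H3K27ac at IFNg-gained regions was 17.0% untreated (16.1 to 17.9) and 58.0% with IFNg (56.8 to 59.2), against 4.83% (4.35 to 5.37) and 19.3% (18.4 to 20.3) in Stat1 KO cells. The control change exceeded the KO change by 26.5 points for H3K27ac, 21.0 for H3K4me1 and 16.3 for PU.1. In the same Stat1 KO cells H3K27ac at TGFb1-gained regions was 29.1 points higher with IFNg than without, and 22.2 points higher at those lacking a panel peak under IFNg, so the KO change was not specific to IFNg regions. H3K4me1 at TGFb1-gained regions changed by 8.99 points in control and -3.57 points in Stat1 KO cells, and PU.1 at TGFb1-gained PU.1 regions by 6.10 and 10.1 points, so part of the H3K4me1 difference was shared with that set. Less these changes, H3K4me1 changed by 8.70 points in control and 0.247 points in Stat1 KO cells, and PU.1 by 17.1 and -3.07 points. The H3K4me1 lists covered 56.3 Mb untreated and 111.5 Mb with IFNg in control cells, and 106.7 and 80.4 Mb in Stat1 KO cells. Each genotype and treatment had 1 library per target, so no test was made, and Stat6 or Stat1 binding in KO cells was not used here to check the genotype. The labels and file names of the Stat6 KO H3K27ac libraries give opposite treatments, so the direction of the H3K27ac change in these cells is uncertain.

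**Figure D2:**
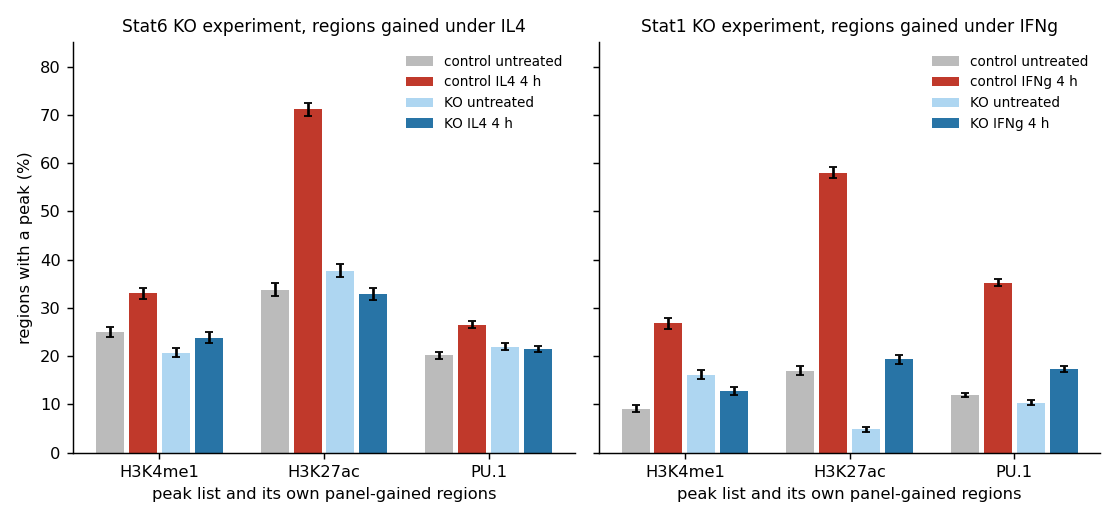
Share of panel-gained regions with a peak, in percent, in the Stat6 KO experiment (left, IL4-gained regions) and the Stat1 KO experiment (right, IFNg-gained regions) for H3K4me1, H3K27ac and PU.1; bars are single libraries and error bars are 95% Wilson intervals. H3K27ac reached 71.1% with IL4 and 58.0% with IFNg in control cells, against 32.8% and 19.3% in KO cells.

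The washouts asked whether gained H3K4me1 outlasts the stimulus. Of 11093 regions gained at 24 h of IL4 over the untreated library of that experiment, 66.0% had a peak at 72 h of IL4 (65.1 to 66.9) and 38.0% after 24 h of IL4 and 48 h of washout (37.1 to 38.9). Peaks shared by the 24 h and untreated libraries had one in 91.7% and 93.5% of cases. Of 12699 regions gained at 24 h of IFNg, 43.4% had a peak at 72 h (42.5 to 44.2) and 34.8% after washout (34.0 to 35.6), with 83.8% and 92.2% for shared peaks. Among the regions with a peak at 72 h, 45.7% (IL4) and 53.6% (IFNg) also had one after washout. For regions gained in both 24 h libraries of each stimulus, and in no untreated library, the shares at 72 h and after washout were 84.3% and 30.0% for IL4 (3152 regions) and 68.9% and 32.2% for IFNg (3066 regions), so IFNg at 72 h moved by more than 1.5 times. These regions lacked a peak in the untreated library by selection. Regions gained in the panel, chosen apart from these libraries, had a peak after washout in 27.0% of cases against 19.8% untreated for IL4. For IFNg the shares were 31.2% against 21.9%. These changes were 4.30 and 9.09 points beyond those at TGFb1-gained regions. Before washout, at 24 h, the same measure was 8.42 points for IL4 and 18.4 points for IFNg. At 72 h of stimulus it was 7.90 and 15.9 points. With 1 library per condition no test was made.

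Binding of the signal-activated factors was compared across the gained sets. Peaks of all stimulated libraries of a factor were pooled, 5 for Stat6, 4 for Stat1 and 1 for JunB, so the shares of Stat6 and Stat1 are higher than at any single time. Stat6 under IL4 bound 17.98% of IL4-gained H3K4me1 regions (17.0 to 19.0), against 6.71% to 12.3% of the sets gained under the other stimuli and 0.319% of the same regions in the only untreated library. Single IL4 libraries gave 9.54% to 13.6%. Stat1 under IFNg bound 14.4% of IFNg-gained regions (13.5 to 15.3), against 5.28% to 12.0% of the other sets, and single IFNg libraries gave 5.84% to 9.23%. JunB under LPS bound 30.3% of LPS-gained regions (29.5 to 31.2), but similar shares of those gained under CpG (30.9%), MALP2 (29.9%) and IFNg (29.9%), and 18.1% of those of IL4. Width-matched peaks that were present before stimulation held Stat6 in 23.9% and Stat1 in 20.6% of cases, above the observed shares, which lay at percentile 0 of 10000 draws for both factors. JunB was at percentile 100 at LPS-gained regions, with 23.5% in the draws.

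Gained regions were partly shared between stimuli. On average 40.0% of the H3K4me1 regions gained under a stimulus had a peak under another, from 15.4% to 58.0% over 56 ordered pairs. Untreated libraries of the other experiments, treated as if stimulated, gave means of 15.7% to 18.4% over the 8 stimuli, with single pairs from 11.1% to 34.9%. In the other direction, single sets of stimulus-gained regions had a peak in 8.18% (129S6) to 29.8% (BALB/c) of cases in these untreated libraries. Independent lists over all 103895 panel regions would give 6.61%. That level is too low, since these regions include untreated peaks, where no gained region can lie. For H3K27ac the mean was 42.5% (7.59% to 79.3%). With untreated libraries treated as if stimulated, the means were 22.4% to 29.5%, and single pairs ran from 18.3% to 36.6%. In the other direction, single sets had a peak in 3.47% (IL4 time course) to 52.0% (BALB/c) of cases in untreated libraries. The level for independent lists, 11.6%, is too low in the same way. MALP2 and CpG shared 78.2% of the H3K27ac regions gained under MALP2 and 78.5% of those gained under CpG, and 79.3% of those of IL1b were found under TNFa. IFNg and LPS formed another pair, with 62.6% of IFNg-gained H3K27ac regions present under LPS and 39.9% of LPS-gained ones under IFNg. Part of the sharing may come from the untreated libraries common to all comparisons, which also enter the levels of the untreated libraries. All 8 stimuli came from the panel, while the untreated libraries set beside them came from other experiments. Sharing between stimuli thus cannot be separated from sharing an experiment. Merged over the stimuli there were 26071 gained H3K4me1 regions, of which 56.3% were gained under 1 stimulus and 271 under all 8. For H3K27ac 52.8% of 20039 were gained under 1 stimulus. LPS, the only stimulus with chromosome Y peaks in the panel, made up 39.5% of the single-stimulus regions for each of these marks. Over pairs without LPS the mean H3K4me1 share was 43.7%.

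**Figure D3:**
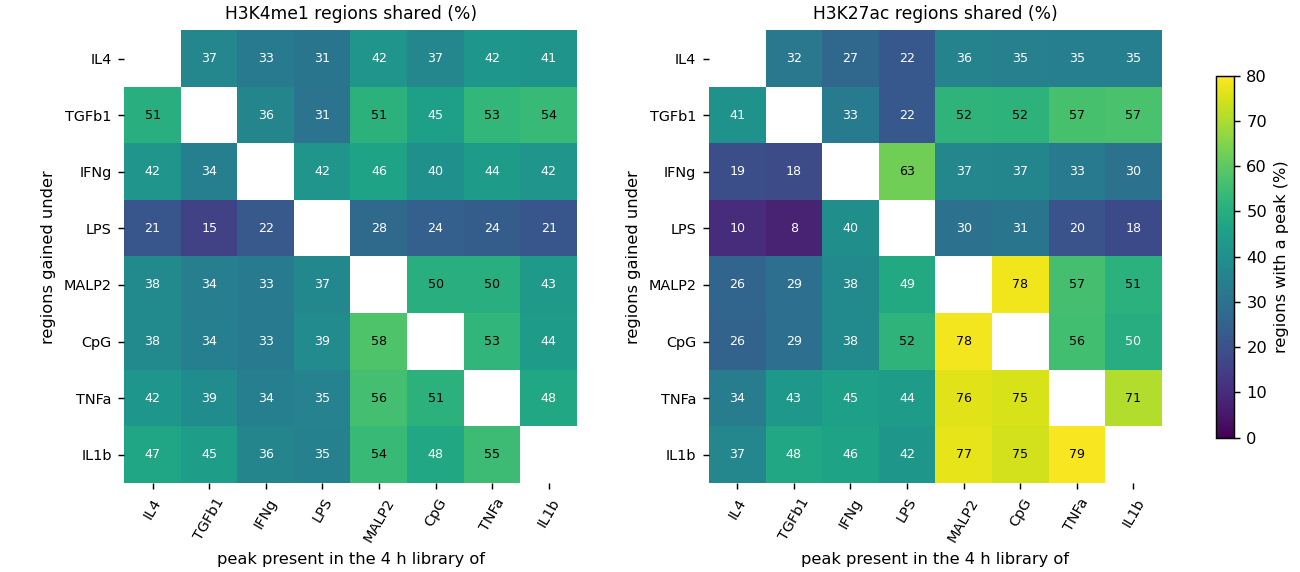
Percent of the regions gained under the stimulus of each line that had a peak in the 4 h panel library of the stimulus of each column, for H3K4me1 (left) and H3K27ac (right). For H3K27ac the squares of MALP2, CpG, TNFa and IL1b reach up to 79.3%, while LPS regions under TGFb1 are at 7.59%.

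In the IL4 time course Stat6 binding and H3K27ac at IL4-gained regions were both higher at 15 min than untreated, while H3K4me1 at IL4-gained regions was at no time above its untreated share. Stat6 peaks numbered 4818 in untreated cells, 23807 at 15 min, 33066 at 1 h and 32673 at 4 h. H3K27ac at IL4-gained H3K27ac regions was 7.09% untreated (6.39 to 7.86), 30.4% at 15 min (29.1 to 31.7), 40.5% at 1 h (39.1 to 41.9) and 41.3% at 4 h (39.9 to 42.7). The label of the 15 min library gives the strain as C57BL/7, read as C57BL/6; at 30 min the share was 30.9%. At the same regions Stat6 was found in 1.02%, 34.4%, 45.3% and 45.4%. Part of the early rise was shared with TGFb1-gained H3K27ac regions, where H3K27ac went from 8.25% untreated to 16.0% at 15 min and 10.5% at 4 h, and Stat6 from 0.929% to 13.9% and 15.6%. H3K4me1 at IL4-gained H3K4me1 regions was 23.5% untreated (22.5 to 24.6), 8.01% at 30 min (7.34 to 8.72), 23.5% at 2 h and 21.9% at 4 h (20.8 to 22.9). Relative to TGFb1-gained regions in the same library it was 1.23 points higher untreated and 5.03 points higher at 4 h. In the IFNg time course Stat1 peaks numbered 4239 untreated and 29641 at 30 min, and H3K4me1 at IFNg-gained regions was 15.0% untreated (14.2 to 16.0), 10.2% at 30 min, 19.0% at 1 h and 25.9% at 2 h (24.8 to 27.1). TGFb1-gained regions in the same libraries were at 14.4%, 9.45%, 16.8% and 20.9%. PU.1 at IFNg-gained PU.1 regions was 5.97% untreated and 15.3% at 2 h, with 8.20% and 10.6% at TGFb1-gained ones. Each time had 1 library, and the low H3K4me1 values at 30 min occurred in both time courses, with TGFb1-gained regions at 8.37% in that of IL4.

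**Figure D4:**
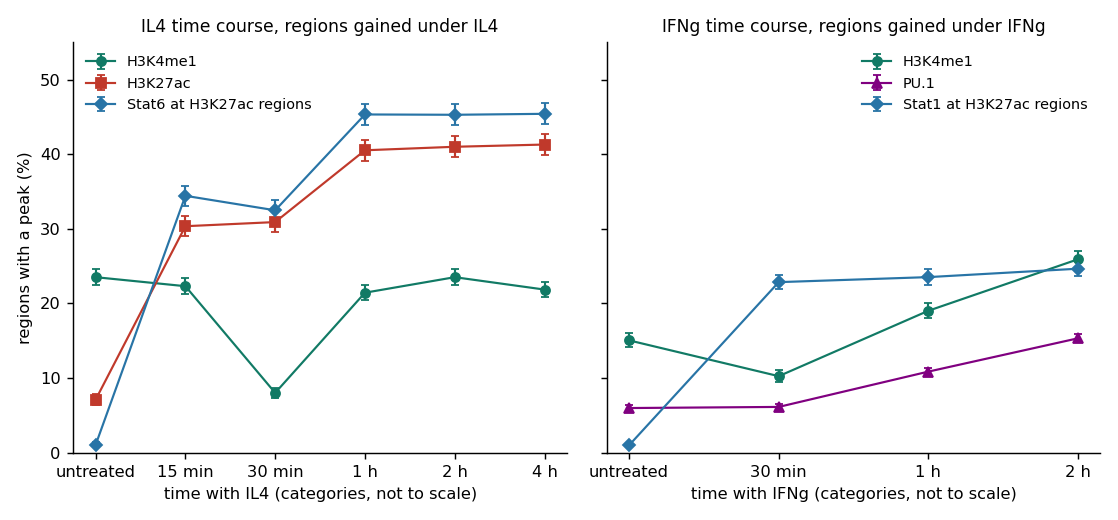
Percent of panel-gained regions with a peak over time of IL4 (left) and IFNg (right), with times as categories; points are single libraries and error bars 95% Wilson intervals. H3K27ac and Stat6 at IL4-gained H3K27ac regions stand at 30.4% and 34.4% at 15 min, while H3K4me1 at IL4-gained H3K4me1 regions lies between 8.01% and 23.5%.

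Fewer of the H3K27ac than of the H3K4me1 regions gained under LPS still had a peak at 24 h. Of the regions gained at 4 h of LPS, 54.8% had H3K4me1 (53.9 to 55.7) and 35.3% had H3K27ac (34.3 to 36.2) at 24 h. The shares were 52.8% for PU.1 (52.1 to 53.6), 48.8% for H3K4me3 (44.6 to 53.0) and 38.3% for RNA polymerase II (37.8 to 38.9). The lists differed in the same direction: peaks present in untreated cells were absent at 24 h in 8.80% of cases for H3K4me1 and 20.9% for H3K27ac, and at 24 h the H3K4me1 list was the longest of its target, with 114362 peaks, and the H3K27ac list the shortest, with 30451. The lower share is therefore not particular to gained regions. At 24 h, 19557 H3K4me1 regions were gained, 17.1% of that library's peaks, of which 30.9% had a peak at 4 h. RNA polymerase II was found at 8.35% of LPS-gained H3K27ac regions in untreated cells (7.81 to 8.92), 17.9% at 4 h (17.2 to 18.7) and 12.9% at 24 h (12.2 to 13.6). The polymerase list at 4 h, with 63724 peaks of a median width of 503 bp, stood apart from the untreated list of 34115, and there was 1 library per time and target.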

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

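The tests of explanations in this part, on the 4 h library of the IL4 time course, were chosen only after the result was seen. The single libraries named here were picked out by fixed rules, of which the one for a sample far from the others picks about 1 in 20 groups by chance.

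Among the 4 wild-type untreated C57BL/6 H3K4me1 libraries outside the panel, that of the IFNg time course stood far below the others: 3.60% of its peaks were absent from both untreated panel libraries, against 6.88% to 7.45% in the other 3. H3K4me1 at IFNg-gained regions changed by -3.32 points with IFNg in Stat1 KO cells and by 17.7 points in 129S6 control cells. Less the changes at TGFb1-gained regions, these values were 0.247 and 8.70 points, and the difference was not tested. H3K27ac at IL4-gained H3K27ac regions changed by -4.85 points with IL4 in Stat6 KO cells and by 37.4 points in BALB/c control cells; the difference was not tested. The file names of these 2 KO libraries give the opposite treatments, so the direction in KO cells is uncertain; with the labels exchanged the change would be positive, and the difference from control cells 32.6 instead of 42.2 points. PU.1 at IL4-gained PU.1 regions changed by -0.489 points with IL4 in Stat6 KO cells and by 6.30 points in control cells; the difference was not tested.

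In the IL4 time course, H3K4me1 at IL4-gained regions changed by -1.66 points from untreated cells to 4 h of IL4, and by 8.02 points in BALB/c control cells; the difference was not tested. Untreated cells in the library labelled 4 h are argued against: its share of IL4-gained minus TGFb1-gained regions was 5.03 points, above the highest of the 6 untreated libraries, at 1.23 points in the untreated library of the same time course. Fewer weak peaks in the 4 h library than in the untreated one remains open and may account for the missing rise, since TGFb1-gained regions, a set from another stimulus, also changed by -5.46 points, and by -4.92 points where they lacked a panel peak under IL4. A weaker or later H3K4me1 response in these cells was not tested.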

How the results depend on the processing

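The alternatives added after seeing the data were the draws matched on score, the share gained without LPS or each untreated library, the subtractions of TGFb1-gained shares, the split by chromosome Y, the pairing by experiment of H3K27ac and PU.1, and the settings applied to replicated regions, newly acetylated regions and H3K27ac at 15 min. Of 161 planned values, 99 stayed within their spread or on their side of the threshold, 56 moved further, 4 lost the call and 2 turned their direction; of 62 added values, 30, 29, 3 and 0 did so. Of these, 20 planned and 2 added values belong to H3K27ac under IL4 and PU.1 under IFNg, where no test can reach 0.05, and count as kept without showing stability; leaving out 1 library, H3K27ac ranged from 19.97 to 36.3 and PU.1 from 1.92 to 14.1 points. Of the lost calls, those within experiments and those for IL4 split by chromosome Y could not reach 0.05 with the libraries left, and say nothing of stability. No paired analysis was possible because of the replicate numbers, of which the groups compared share fewer than 2; pairing by experiment, which the labels name, was run instead. Leaving out each library in turn changed no call of the 3 comparisons that passed the test, with exact permutation p of 0.00476 to 0.0238 for IL4-gained, 0.00794 to 0.0119 for IFNg-gained and 0.0179 to 0.0286 for IL4 against IFNg. The latter passed under every alternative run for it. The difference in the share gained was 0.692 to 1.97 points without 1 untreated library, with exact permutation p of 0.115 to 0.461. The cause was not tested for any shift below. Depth is unknown, so weak peaks missed in a list cannot be separated from absent ones, and single libraries limit all values without a test.

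With the untreated library of the same file style only, the IL4 difference was 15.9 points (exact permutation p = 0.0541), the IFNg difference 14.0 (exact p = 0.138) and the share gained -2.09 points (exact p = 0.131). Latent regions numbered 7173 for IFNg, 7220 for IL4, 7859 for TNFa, 5960 for TGFb1, 6234 for IL1b, 9379 for MALP2 and 8966 for CpG. Control minus KO changes were 36.0 (Stat6, H3K27ac), 4.89 (Stat6, PU.1), 28.1 (Stat1, H3K4me1), 21.6 (Stat1, H3K27ac) and 14.5 points (Stat1, PU.1). Stat1 bound 15.7% of IFNg-gained and JunB 28.4% of LPS-gained regions.

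With a score of at least 100 the share gained was -0.729 points (exact p = 0.479). Latent regions numbered 4067 for LPS, 2662 for IFNg, 3971 for MALP2 and 3285 for CpG. Control minus KO changes of H3K4me1 were 7.32 (Stat6) and 24.4 points (Stat1), with 23.0 for H3K27ac and 14.8 for PU.1 (both Stat1). Stat6 bound 16.7% and Stat1 13.2%. IL4 regions had a peak in 36.2% after washout and 68.2% at 72 h, IFNg regions in 40.7% at 72 h.

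With an overlap of 50% of the shorter peak the Stat1 difference of H3K4me1 was 19.0 points. Stat6 bound 15.0%, Stat1 10.7% and JunB 25.3%. Washout and 72 h shares were 34.9% and 61.8% for IL4 and 33.0% and 40.5% for IFNg. LPS regions had H3K4me1 in 53.2% and polymerase in 37.2% at 24 h.

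More than 1000 bp from an untreated peak, latent regions numbered 4398 for LPS, 2415 for IFNg, 2671 for IL4, 2977 for TNFa, 2048 for TGFb1, 2192 for IL1b, 3533 for MALP2 and 3403 for CpG. The Stat1 difference of H3K4me1 was 19.1 points. Stat6 bound 20.6%, Stat1 15.8% and JunB 33.3%. IL4 regions had a peak in 67.4% at 72 h and IFNg regions in 32.5% after washout.

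For regions in both 24 h libraries, washout and 72 h shares were 30.0% and 84.3% (IL4) and 32.2% and 68.9% (IFNg). With exchanged Stat6 KO labels the H3K27ac difference was 32.6 points. Within experiments the IL4 difference was 10.4 and the IFNg difference 19.7 points (exact sign-flip p = 0.5 for each), with 35.7 for H3K27ac under IL4 and 15.2 for PU.1 under IFNg (exact sign-flip p = 0.5 for each, the smallest possible). Libraries lacking Y peaks gave 31.0 points for IL4 (exact p = 0.1, the smallest possible) and 22.6 for IFNg (exact p = 0.0571), and libraries with Y peaks 6.88 for IL4 (exact p = 0.6); fewer libraries entered each. With equal numbers of peaks the differences were 13.3 (IL4) and 17.3 points (IFNg), and minus the TGFb1-gained share 8.33 and 17.1 points, or 14.6 and 20.6 points with only TGFb1-gained regions lacking a panel peak under the stimulus, each still past the threshold. Against draws matched also on score, Stat6 differed by -3.51, Stat1 by -4.01 and JunB by 10.1 points.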

Other observations

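All tests of explanations on chromosome Y in this part were chosen only after the result was seen; both tests on Stat1 KO cells were fixed before their results were seen, apart from the comparison of total peak numbers, which was added later.

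Most regions that gained H3K27ac were already marked by H3K4me1 before stimulation, with LPS as the exception. Among H3K27ac regions gained at 4 h and without H3K4me3, 82.6% had H3K4me1 in untreated cells for TGFb1 (81.3 to 83.9), 81.8% for IL1b, 76.7% for TNFa, 71.3% for both IL4 and MALP2, 66.8% for CpG and 61.5% for IFNg (60.3 to 62.7). Under LPS the share was 45.1% (44.0 to 46.1). Of the LPS regions without H3K4me1 before, 4904 in all, 30.4% had it at 4 h, and of the 587 of TGFb1 55.4% did. Under IFNg 59.2% of such regions had PU.1 at 4 h, and under LPS 28.6%. The LPS PU.1 list had narrower peaks (median width 498 bp, 62.5 Mb covered) than that of IFNg (741 bp, 89.8 Mb). This favours fewer overlaps under LPS.

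Most regions that had both marks new at 4 h of LPS and no H3K27ac peak at 24 h still held H3K4me1. Of 1493 regions with both marks new at 4 h of LPS, 983 (65.8%, 63.4 to 68.2) had no H3K27ac peak at 24 h, and 833 of these (84.7%, 82.4 to 86.9) held H3K4me1 at 24 h. Where H3K27ac was still found, 97.5% did (95.7 to 98.5), so H3K4me1 was absent more often where H3K27ac was. The H3K4me1 list at 24 h was the longest of its target, with 114362 peaks, and the H3K27ac list the shortest, with 30451, which favours finding H3K4me1. Stat6, pooled over 5 IL4 libraries, bound 55.6% of IL4-gained H3K27ac regions (54.1 to 56.98), or 45.4% in the 4 h library alone, against 20.6% (LPS) to 30.8% (IL1b) of the other sets. Stat1, pooled likewise, bound 34.9% of IFNg-gained ones (33.7 to 36.0), against 17.6% (TGFb1) to 24.8% (LPS). JunB under LPS bound 70.6% of the IL1b set, 69.9% of the CpG set and 59.7% of the LPS set itself, with 42.7% for IL4.

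The panel without polymerase held 12 libraries with peaks on chromosome Y, all of them LPS or untreated, and 32 with 0. Chromosome Y left out in part of the processing is argued against by 6 H3K27ac regions on chromosome X that had a peak in all 12 H3K27ac libraries without Y peaks and in none of the 13 with them; 0 autosomal regions did so. Of these, 5 lay between 47933333 and 47965843 and the other at 100676032 to 100679624. Cells of male mice in some libraries and of female mice in others may account for the split, since 8 such PU.1 regions lay on X and 1 on an autosome, and the share of PU.1 peaks on X was 2.16% to 2.49% with and 2.77% to 2.94% without Y peaks. The other targets were less clear: 23 H3K4me3 regions on X but also 252 on autosomes, and 0 H3K4me1 regions, split this way, and X shares overlapped for H3K4me1, H3K27ac and H3K4me3. The labels used here give no sex, the split coincides with LPS in the panel, and other differences between the libraries remain open.

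In Stat1 KO cells, H3K27ac at IFNg-gained regions was 14.5 points higher with IFNg than without. A response to IFNg without Stat1 as the whole cause is argued against, since TGFb1-gained H3K27ac regions changed by 29.1 points and the IFNg set minus the TGFb1 set by -14.6 points, or -7.71 points with only TGFb1-gained regions that lacked a panel peak under IFNg. Fewer weak peaks in the untreated than in the IFNg library could raise both sets and cannot be told apart from another difference between these libraries. TGFb1-gained regions had a peak in 12.0% of cases in untreated Stat1 KO cells and 41.1% with IFNg. Untreated cells gave 41.5% in 129S6 and 52.0% in BALB/c, but 8.25% in the IL4 time course. The 26.5 points between control and KO changes of H3K27ac rest on the low untreated KO library. The number of H3K27ac peaks differed by only 663, while 1065 more of the TGFb1-gained regions had a peak with IFNg, and there was 1 library per condition.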
